A study of Mus musculus with 16 samples.

How the data were processed

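The series holds 16 arrays of sorted naive mouse T cells on a C57BL/6 background, in 6 groups: wild-type and Tsc1-deficient CD4 cells, unstimulated and after 4 h on plate-bound antibodies against CD3 and CD28 (3 arrays each), and wild-type and Tsc1-deficient unstimulated CD8 cells (2 arrays each). Grouping follows the genotype, cell type and stimulation in the labels. The treatment text of the labels names a different deficient strain in 1 sentence and Tsc1 in the next, while every genotype entry and title names Tsc1, and the latter were followed. The values are log2 signals that the submitters' processing notes credit to RMA in Partek 6.5, made by the authors before deposit and used as deposited. The table median is 3.36, and replicate arrays correlate at 0.992 to 0.997. Raw scans were not used here. The genome build is not given in the sources used here, so no coordinates were used.

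Of 45141 probe sets, 104 are controls, 28898 name 1 gene in the platform's table, 551 name several and 15588 have no gene name there. Probe sets that name 1 gene were kept, and for each gene the probe set with the highest mean over all arrays, which left 17097 genes, 7180 of them with more than 1 probe set. Entrez identifiers of 28689 of these probe sets were checked against a RefSeq gene table, and 0 symbols changed.

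Differences of group means were tested with limma 3.58.1 in R 4.3.3. All 16 arrays entered 1 linear model with a mean per group (10 residual degrees of freedom), and variances were moderated across genes (prior SD 0.146, prior degrees of freedom 6.23). P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene is called at adjusted p under 0.05. Comparisons were genotype in each of 3 conditions, stimulation in each genotype, and 2 differences of differences. These choices, the gene lists and most alternatives were fixed before the data were examined.

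The 15 pathway lists and 11 lists of cell type markers (449 of 519 entries measured) were tested with camera at its preset correlation of 0.01, adjusted over the 26 lists of a comparison. The alternatives were camera with the correlation estimated from the residuals, and fry. Further gene families were chosen after the results were seen and appear only under other observations. The rule for named genes took called genes whose arrays did not overlap between the groups (not asked of the differences of differences), whose higher mean exceeded the table median, and which have a probe set for 1 gene. From these it took the 10 highest and 10 lowest changes (5 and 5 for the differences), besides Tsc1 and up to 4 members of each list by absolute change. Not every list member so taken is printed. Expected overlaps of called genes are the product of the list sizes over the number of genes. Correlations between comparisons were set against 100 simulated sets of unchanged groups with the same shared arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

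The pipeline was tested on simulated data with the arrays' own spread and 100 genes changed by 0.5 and 100 by 1 on the log2 scale. The changed genes were drawn from those above the median mean level, so the shares called do not cover dimmer genes. The noise was independent between genes and arrays. In unstimulated CD4 cells 46% and 96% of these were called, in stimulated CD4 cells 49% and 94%, and in CD8 cells 21% and 87%. For stimulation it was 54% and 97% in wild-type and 42% and 90% in deficient cells, for the difference of the responses 14% and 72%, and for the difference between the lineages 3% and 57%. False calls numbered between 1 and 8 per comparison, with no deviations shared between genes in the simulation.

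Control probe sets for the 3' and 5' ends of Gapdh differed by 0.96 on the log2 scale on stimulated deficient CD4 replicate 1 and by 0.64 on deficient CD8 replicate 2, against 0.02 to 0.40 on the other 14 arrays. Both stayed in, and each comparison was also made without them, an alternative chosen after the control probe sets were seen, as was the Gapdh difference as a covariate. The mean of the lysosome list per array was also fitted by a linear model of the 6 groups, with and without that covariate. The other alternatives were averaged probe sets, all probe sets tested, a filter on dim genes, quantile normalization, median centring, an intensity trend with a robust prior, array weights, a fit of the compared groups alone, a 2-fold threshold, blocks of arrays, and each array left out in turn.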

Results

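Naive T lymphocytes sorted from C57BL/6 mice with and without functional Tsc1 were profiled on 16 single-colour Affymetrix expression arrays that fall into 6 groups. CD4 cells were measured unstimulated (0 h) and after 4 h on plate-bound antibodies against CD3 and CD28, with 3 arrays per genotype at each time. CD8 cells were measured unstimulated, with 2 arrays per genotype. Tsc1 encodes a subunit of the TSC complex, a brake on the growth-promoting kinase complex mTORC1, and the comparisons ask which transcripts depend on it in resting T cells and early in activation. The number of arrays limits the precision. The labels do not say that the arrays of a group come from separate mice, so the p-values measure the spread between these arrays, which may be technical. Changes are differences of mean log2 signal, given with their standard error (±), and p-values are adjusted over all genes of a comparison unless another family is named.

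Tsc1 itself was lower in the deficient cells by the brightest of its 3 probe sets. Its signal was 7.31 ± 0.07 (SD, n = 3) in unstimulated wild-type CD4 cells and 6.49 ± 0.06 (SD, n = 3) in deficient ones, a change of -0.83 ± 0.10 (adjusted p = 0.000122 over all probe sets). In stimulated CD4 cells it was 7.46 ± 0.09 (SD, n = 3) in wild-type and 6.39 ± 0.15 (SD, n = 3) in deficient cells, a change of -1.06 ± 0.10 (adjusted p = 1.75e-05). In CD8 cells it was 6.94 ± 0.07 (SD, n = 2) and 6.38 ± 0.04 (SD, n = 2), a change of -0.55 ± 0.12 (adjusted p = 0.0164). The ranges of the genotypes did not overlap in any of these comparisons. The second brightest probe set changed by -0.13, -0.21 and 0.10 in the same order (adjusted p = 0.801, 0.576 and 0.887), and the dimmest by -0.19, 0.03 and 0.08 (adjusted p = 0.602, 0.956 and 0.898). Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here. The CD8 call for Tsc1 was lost without wild-type CD8 replicate 1 (-0.50, adjusted p = 0.109) and with the probe sets averaged (-0.13, adjusted p = 0.554).

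**Figure D1:**
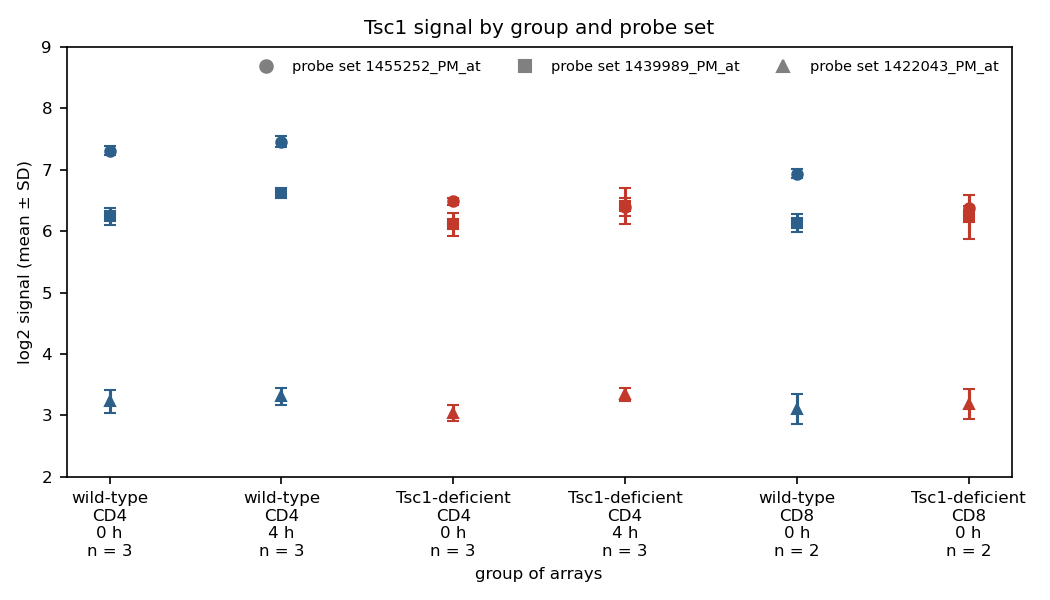
Mean log2 signal (y axis, ± SD) of the 3 Tsc1 probe sets in the 6 groups of arrays (x axis, blue wild-type, red Tsc1-deficient). The brightest probe set lies between 6.94 and 7.46 in the wild-type groups and between 6.38 and 6.49 in the deficient groups.

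Unstimulated Tsc1-deficient CD4 cells (n = 3) held more transcript of lysosome and sterol synthesis genes than wild-type cells (n = 3). Ccr9, a chemokine receptor that guides T cells to the small intestine, rose by 3.94 ± 0.19 (15.4-fold, adjusted p = 3.5e-09). Rragd, a Rag GTPase that helps place mTORC1 on the lysosome, rose by 2.87 ± 0.21 (7.32-fold, adjusted p = 4.03e-07). Igfbp4, a binding protein for insulin-like growth factors, fell by 2.24 ± 0.20 on the log2 scale (adjusted p = 2.57e-06). Of 17097 genes tested, 997 passed limma's test at adjusted p under 0.05, 677 higher and 320 lower, and 161 of them changed at least 2-fold.

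Other genes that rose strongly at rest were Fam221a (3.69 ± 0.17), the efflux transporter Abcb1a (3.63 ± 0.20), the prostaglandin synthase Hpgds (3.01 ± 0.18), the proprotein convertase Pcsk1 (2.61 ± 0.25), the mitotic kinesin Kif23 (2.47 ± 0.26), Patl2 (2.40 ± 0.21) and the ion channel Trpm1 (2.39 ± 0.16). Genes that fell included Lrrc75b (-1.93 ± 0.15), the adhesion molecules L1cam (-1.52 ± 0.10) and Amigo2 (-1.48 ± 0.19), Ggt5 (-1.35 ± 0.14), Gprasp1 (-1.33 ± 0.11), Tent5a (-1.32 ± 0.19), Pdlim4 (-1.18 ± 0.12), Pcbp4 (-1.14 ± 0.16) and the interleukin-18 receptor chain Il18r1 (-1.14 ± 0.09). Hpgds and Pcsk1 in wild-type cells and Lrrc75b in deficient cells lay below the table median, where a signal may be near background, so the size of their changes is uncertain. Each of these genes passed limma's test with non-overlapping arrays, which chance gives for 10% of genes with 3 arrays against 3.

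Of 21 measured lysosome and autophagy genes, 14 rose at rest and 0 fell (15 and 0 adjusted over the list alone), and the list stood above other genes (camera, adjusted p = 1.08e-15, and adjusted p = 0.00385 with an estimated correlation). Its leading members were the protease Ctsl (1.36 ± 0.18), the membrane protein Lamp2 (1.18 ± 0.12) and the glycosidase Hexa (0.95 ± 0.10). Of 22 sterol and fatty acid synthesis genes, 12 rose and 0 fell (19 and 0 adjusted over the list alone), with an adjusted p of 7.39e-15 and adjusted p = 0.00385 with an estimated correlation. Cyp51 (1.29 ± 0.14), Fdps (0.91 ± 0.18) and Sqle (0.81 ± 0.14), all enzymes of the cholesterol pathway, led it. Of 28 mitosis genes, 10 rose and 0 fell (21 and 0 adjusted over the list alone), with an adjusted p of 6.09e-16 but adjusted p = 0.0659 with an estimated correlation. Ube2c (1.90 ± 0.31), Ccnb2, a mitotic cyclin (1.69 ± 0.21), the proliferation marker Mki67 (1.68 ± 0.15) and Birc5 (1.62 ± 0.25) led the mitosis genes, with Ccnb2 and Birc5 below the table median in wild-type cells. DNA replication and S phase genes rose in 7 of 28 cases (8 adjusted over the list alone), among them Rrm2 (1.72 ± 0.17) and Uhrf1 (1.39 ± 0.18). That list had an adjusted p of 3.99e-07 and adjusted p = 0.0764 with an estimated correlation.

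Of 19 mTOR pathway components, Rragd, the GTPase regulator Flcn (0.93 ± 0.17) and the stress-induced mTORC1 inhibitors Sesn1 (0.61 ± 0.15) and Sesn2 (0.59 ± 0.16) rose and 0 fell (5 and 0 adjusted over the list alone). The list had an adjusted p of 0.000477, and adjusted p = 0.0739 with an estimated correlation. The calls rested on single arrays for Sesn1 (adjusted p = 0.0633 to 0.0982 without any array but deficient replicate 2) and Sesn2 (0.0621 to 0.153 without any but wild-type replicate 2). Amino acid and tRNA charging genes, targets of the transcription factor ATF4, rose in 7 of 25 cases (8 higher and 1 lower adjusted over the list alone), led by Trib3 (0.83 ± 0.12). Oxidative phosphorylation genes rose in 5 of 26 cases (8 adjusted over the list alone), led by Cox5b (0.53 ± 0.10). The ATF4 list had an adjusted p of 0.0066 and adjusted p = 0.263 with an estimated correlation. The oxidative phosphorylation list had 9.12e-07 and adjusted p = 0.202 with an estimated correlation. Among 17 glycolysis genes only the aldolase Aldoc passed (1.54 ± 0.15, 4 genes adjusted over the list alone), with a list p of 0.0081 and adjusted p = 0.234 with an estimated correlation.

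Naive T cell quiescence and homing genes stood lower as a list at rest (adjusted p = 0.00659, and adjusted p = 0.11 with an estimated correlation). Of 21 measured, Bach2 (-0.61 ± 0.13) and Runx1 (-0.46 ± 0.09) fell, while Tob1, known to restrain proliferation, rose (1.10 ± 0.15), and 1 was higher and 3 lower adjusted over the list alone. Bach2 lost its call without wild-type replicate 1 (adjusted p = 0.0535) or deficient replicate 1 (0.0514), and Runx1 with its probe sets averaged (-0.23, adjusted p = 0.104). Effector and memory genes moved both ways. Of 28, 9 rose, among them the S100 protein S100a6 (1.57 ± 0.24), the lectin-like receptor Klrd1 (1.42 ± 0.11) and the chemokine receptor Cxcr3 (1.22 ± 0.26), and 3 fell, namely Il18r1, the memory marker Cd44 (-0.997 ± 0.12) and perforin, Prf1 (-0.85 ± 0.23), the last no longer called without any array but deficient replicate 1 (adjusted p = 0.0621 to 0.14). Adjusted over the list alone, 15 were higher and 4 lower, and the list p was 0.000597, with adjusted p = 0.202 with an estimated correlation. In the immediate early list, Bhlhe40 (2.003 ± 0.20) and Irf4 (0.96 ± 0.14), transcription factors induced by antigen receptor signals, rose without stimulation, though the list of 25 did not pass (adjusted p = 0.607).

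Markers of other cells were measured alongside these groups. Ngp, a neutrophil granule gene, rose by 2.64 ± 0.67 (adjusted p = 0.0277), the only one of 11 neutrophil genes to pass (6 adjusted over the list alone), with a list p of 0.00189 and adjusted p = 0.389 with an estimated correlation. Without Tsc1-deficient replicate 3 its change was 1.82 (adjusted p = 0.134), and it was also lost without wild-type replicate 1 (2.51, adjusted p = 0.0931) or replicate 2 (2.08, adjusted p = 0.15). CD8 lineage genes were lower in deficient CD4 cells, with Cd8a (-0.84 ± 0.21) and Runx3 (-0.55 ± 0.10) falling among 5 (3 adjusted over the list alone, list p 0.000828, and adjusted p = 0.0764 with an estimated correlation). Cd8a was -0.56 without wild-type replicate 1 (adjusted p = 0.122) and lost its call without any 1 deficient array (0.0692 to 0.0893), and Runx3 lost it with its probe sets averaged (-0.33, adjusted p = 0.0888). In the NK or NKT list of 9, granzyme A, Gzma, rose (1.20 ± 0.31) and Prf1 fell (4 higher and 1 lower adjusted over the list alone, list p 0.0446, adjusted p = 0.231 with an estimated correlation, and 0.0894 without the 2 arrays with high 3' to 5' ratios), and the call of Gzma was lost without any array but deficient replicate 1 (adjusted p = 0.0582 to 0.145). The 12 regulatory T cell genes gave an adjusted p of 0.655, with Nrp1 higher (1.64 ± 0.22) and Capg lower (-0.61 ± 0.12). No monocyte, macrophage or dendritic cell gene of 15 passed limma's test, at 0 adjusted over the list alone (list p 0.071), and CD4 lineage genes did not pass either (0.349). Lists that did not pass were ribosome biogenesis (adjusted p = 0.264), apoptosis (0.284), activation cytokines (0.349), interferon response (0.481), B cell (0.198), gamma delta T cell (0.107), erythroid (0.188), platelet (0.439) and immature thymocyte genes (0.656).

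The count of 997 genes depended on the arrays in the fit. It was 1723 without the 2 arrays with high 3' to 5' ratios, both in other groups, with all 997 among them, and it was 625 without wild-type replicate 2, 606 without wild-type replicate 3, 589 without deficient replicate 1 and 610 without deficient replicate 2.

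**Figure D2:**
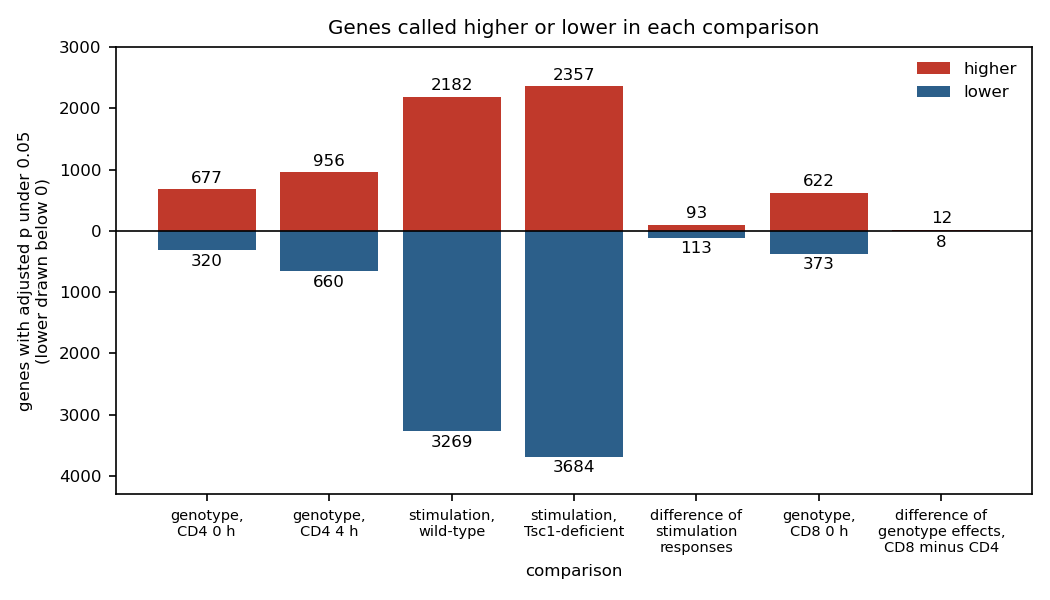
Number of genes that passed limma's test at adjusted p under 0.05 (y axis, higher drawn above 0 in red and lower below 0 in blue) in each of the 7 comparisons (x axis). Stimulation called 5451 genes in wild-type and 6041 in Tsc1-deficient CD4 cells, against 997 genes between the genotypes at rest.

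After 4 h of stimulation, Tsc1-deficient CD4 cells (n = 3) held more transcript of the cytokine genes Ifng (2.07 ± 0.23, 4.21-fold), Il4 (1.69 ± 0.18) and Csf2 (1.27 ± 0.17) than wild-type cells (n = 3). The homing receptor S1pr1, which lets T cells leave lymph nodes, was lower (-1.28 ± 0.14). Abcb1a (3.69 ± 0.20, 12.9-fold, adjusted p = 2.46e-08), Rragd (2.995 ± 0.21) and Mki67 (2.26 ± 0.15) were higher, as at rest. In wild-type cells Il4, Csf2 and Mki67 lay below the table median, so the size of their changes is uncertain. Limma called 1616 genes, 956 higher and 660 lower, and 195 of them changed at least 2-fold. Without the 2 arrays with high 3' to 5' ratios it called 1798, of which 1286 were among the 1616.

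Other genes that rose were the neutrophil genes S100a8 (3.12 ± 0.64), Ngp (3.03 ± 0.67), S100a9 (2.89 ± 0.60) and Camp (2.48 ± 0.52), as well as Plac8 (2.36 ± 0.35), the acyl-CoA thioesterase Acot7 (2.32 ± 0.22) and Pcsk1 (2.22 ± 0.25). Hs3st3b1 (-1.65 ± 0.19), the EGR corepressor Nab2 (-1.64 ± 0.18), the transcriptional inhibitor Id3 (-1.60 ± 0.25), the atrophy-related ubiquitin ligase subunit Fbxo32 (-1.497 ± 0.16), Rhebl1, a relative of the mTORC1 activator Rheb (-1.48 ± 0.13), and Spred2, an inhibitor of MAP kinase signalling (-1.47 ± 0.19), fell. Ctse (-1.35 ± 0.20), Hivep3 (-1.34 ± 0.16), the T cell receptor segment Trav6-3 (-1.34 ± 0.18) and Crebrf (-1.33 ± 0.18) fell too. Camp and Pcsk1 lay below the table median in wild-type cells.

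Of 26 activation cytokines and receptors, 9 rose and 1 fell, the chemokine Xcl1 (-0.79 ± 0.21), with 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.000181, and adjusted p = 0.0157 with an estimated correlation). Il2 was at 6.80 in deficient and 7.13 in wild-type stimulated cells (adjusted p = 0.406). Quiescence and homing genes fell in 7 of 21 cases and rose in 2 (11 lower and 2 higher adjusted over the list alone, adjusted p = 6.32e-05, and adjusted p = 0.0296 with an estimated correlation). Besides S1pr1, the naive T cell factor Lef1 fell (-0.83 ± 0.12), while Tob1 (0.78 ± 0.15) and the integrin Itgb7 (0.92 ± 0.14) rose. Of 28 effector and memory genes, 12 rose and 2 fell (17 and 3 adjusted over the list alone, adjusted p = 2.23e-07, and adjusted p = 0.0472 with an estimated correlation), led by the T-box factor Eomes (1.76 ± 0.36), S100a6 (1.62 ± 0.24), Gzma (1.61 ± 0.31, from below the table median) and Cxcr3 (1.28 ± 0.26).

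Mitosis genes rose in 16 of 28 cases (25 adjusted over the list alone, adjusted p = 1.29e-17, and adjusted p = 0.0296 with an estimated correlation), led by Mki67, Ube2c (1.96 ± 0.31), Birc5 (1.49 ± 0.25) and Top2a (1.45 ± 0.20), all but Top2a below the table median in wild-type cells. DNA replication genes rose in 4 of 28 cases and 1 fell (5 and 2 adjusted over the list alone, adjusted p = 0.0403, and adjusted p = 0.394 with an estimated correlation). The lower gene was Mcm7 (-0.51 ± 0.14), no longer called without the 2 arrays (-0.33, adjusted p = 0.0744), wild-type replicate 1 (0.114) or 2 (0.0613) or deficient replicate 1 (0.101). Lysosome genes rose in 13 of 21 cases (13 higher and 1 lower adjusted over the list alone, adjusted p = 8.07e-10, and adjusted p = 0.0157 with an estimated correlation), with Gla at 1.78 ± 0.20 and Ctsl at 1.12 ± 0.18. Sterol and fatty acid genes rose in 12 of 22 cases (13 adjusted over the list alone, adjusted p = 2.61e-09, and adjusted p = 0.0157 with an estimated correlation), led by the desaturase Scd1 (0.89 ± 0.21), Elovl6 (0.86 ± 0.17) and Mvd (0.83 ± 0.12). Glycolysis genes rose in 7 of 17 cases (7 adjusted over the list alone, adjusted p = 4.71e-06, and adjusted p = 0.0473 with an estimated correlation), led by Tpi1 (1.02 ± 0.12) and Aldoc (0.93 ± 0.15, from below the table median). ATF4 target genes rose in 9 of 25 cases (10 adjusted over the list alone, adjusted p = 5.65e-08, and adjusted p = 0.0454 with an estimated correlation), led by the serine synthesis enzymes Psph (1.11 ± 0.14) and Phgdh (0.90 ± 0.13).

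Interferon response genes rose in 10 of 23 cases in stimulated cells (19 adjusted over the list alone, adjusted p = 3.75e-10, but adjusted p = 0.257 with an estimated correlation), led by Ifit3 (1.66 ± 0.38) and Usp18 (1.65 ± 0.30). Without the 2 arrays with high 3' to 5' ratios Ifit3 was at 1.497 (adjusted p = 0.0571), and without wild-type replicate 1 at 1.37 (adjusted p = 0.0636). In the apoptosis list (adjusted p = 0.0932), 6 of 21 genes rose, among them the death-promoting Bcl2l11 (0.82 ± 0.11) and Fasl (0.82 ± 0.17) and the protective Bcl2l1 (0.84 ± 0.18), and the death-promoting Bbc3 fell (-0.76 ± 0.13), with 7 higher and 1 lower adjusted over the list alone. With their probe sets averaged Bcl2l1 (0.25, adjusted p = 0.127) and Fasl (0.496, adjusted p = 0.0735) were not called. The mTOR list did not pass (adjusted p = 0.169), though Ddit4, an inhibitor of mTORC1 signalling, rose (1.21 ± 0.24). The neutrophil list had 4 genes higher of 11 (4 adjusted over the list alone, adjusted p = 0.000926, and adjusted p = 0.353 with an estimated correlation), and the regulatory T cell list had 3 higher and 1 lower of 12 (6 and 1 adjusted over the list alone, adjusted p = 0.0293, and adjusted p = 0.179 with an estimated correlation). The B cell list passed with 0 of 13 genes called by limma, 0 adjusted over the list alone, at adjusted p = 0.00664, and adjusted p = 0.257 with an estimated correlation. Of 15 myeloid markers, Lyz2 (1.18 ± 0.31) and Mpeg1 (0.83 ± 0.22) rose (list adjusted p = 0.0532). Both lost their calls without wild-type replicate 1 (adjusted p = 0.0867 and 0.069), wild-type replicate 2 (0.0781 and 0.111) or deficient replicate 3 (0.0935 and 0.0913), and Mpeg1 also without deficient replicate 2 (0.0767).

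Replicate 1 of this deficient group stood apart in RNA quality. Its Gapdh 3' probe set exceeded the 5' one by 0.96 on the log2 scale, against 0.02 to 0.40 on 14 other arrays. Without wild-type stimulated replicate 2, limma called 1062 genes, and 823 when only the compared groups entered the fit.

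**Figure D3:**
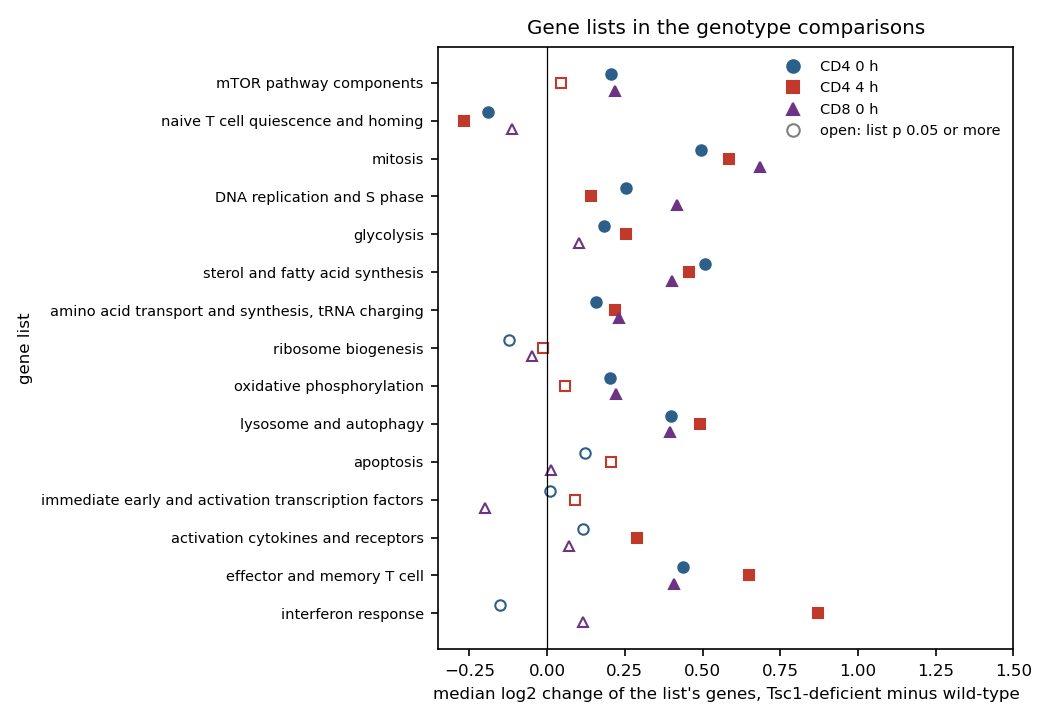
Median log2 change, Tsc1-deficient minus wild-type (x axis), of the genes of 15 pathway lists (y axis) in unstimulated CD4 (blue circles), stimulated CD4 (red squares) and unstimulated CD8 cells (purple triangles). Filled symbols are lists with camera adjusted p under 0.05 at the preset correlation, and the lysosome list has medians of 0.40, 0.49 and 0.40.

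Stimulation of wild-type CD4 cells (n = 3 at each time) asks how naive cells respond to receptor and costimulation signals within 4 h. Irf4, a transcription factor of activated lymphocytes, rose by 6.51 ± 0.14 (91.4-fold, adjusted p = 1.23e-14), and the cytokine gene Il2 rose by 5.01 ± 0.21, from a level of 2.11 that lies below the table median. The chemokine gene Cxcl10 (4.82 ± 0.37) and the orphan nuclear receptor Nr4a3 (4.78 ± 0.21) rose as well. Dtx1, a Notch pathway gene linked to T cell anergy, fell by 4.94 ± 0.13 on the log2 scale. Limma called 5451 genes, 2182 higher and 3269 lower, with 1526 changed at least 2-fold, and 6209 without the 2 arrays with high 3' to 5' ratios. With all probe sets tested the balance was near even, at 6000 higher and 6112 lower.

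Other strong rises were those of Zfp948 (4.59 ± 0.25), the AP-1 factor Fosl2 (4.43 ± 0.19), Nr4a2 (4.42 ± 0.44), Plagl1 (3.77 ± 0.21) and the chemokines Xcl1 (3.67 ± 0.21) and Ccl3 (3.49 ± 0.20). Slc16a5 (-5.01 ± 0.17), Afp (-4.87 ± 0.16), Ccdc69 (-4.83 ± 0.13), Pdlim4 (-4.76 ± 0.12), Igfbp4 (-4.43 ± 0.20), the iron exporter Slc40a1 (-4.24 ± 0.34), Ampd3 (-4.22 ± 0.19), Septin9 (-4.00 ± 0.12) and Sema4a (-3.72 ± 0.18) fell. Slc16a5, Afp, Slc40a1 and Ampd3 ended below the table median, and Zfp948, Plagl1 and Ccl3 began there, so these changes may be larger than given and their order is uncertain. Of 26 activation cytokines and receptors, 20 rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p = 2.3e-12, and adjusted p = 0.000212 with an estimated correlation). Of 25 immediate early genes, 15 rose and 3 fell (15 and 3 adjusted over the list alone, adjusted p = 2.16e-06, but adjusted p = 0.554 with an estimated correlation). Fos, a first-wave gene, was already at 11.4 at rest and fell by 2.73 ± 0.44 on the log2 scale.

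Effector and memory genes fell in 11 of 28 wild-type cases and rose in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.00417, but adjusted p = 0.567 with an estimated correlation), with Nkg7 (-2.57 ± 0.23) and Prf1 (-2.48 ± 0.23) lower and the T-box factor Tbx21 higher (1.87 ± 0.24, from below the table median). Cd44 fell by 1.22 ± 0.12 on the log2 scale. CD8 lineage genes fell in 4 of 5 cases (4 adjusted over the list alone, adjusted p = 0.00347, but adjusted p = 0.268 with an estimated correlation). Myeloid markers fell in 11 of 15 cases, Mpeg1 (-2.17 ± 0.22), Lyz2 (-2.14 ± 0.31) and Tyrobp (-2.13 ± 0.33) among them (11 adjusted over the list alone, adjusted p = 0.00417, but adjusted p = 0.57 with an estimated correlation). Other lists split. Quiescence genes rose in 5 and fell in 7 of 21 cases (adjusted p = 0.519), with Itgb7 at -3.18 ± 0.14 and the survival gene Bcl2 at -2.17 ± 0.14, and sterol genes rose in 2 and fell in 10 of 22 (adjusted p = 0.0953). No culture of 4 h without stimulation is among the groups, so changes from the antibodies and changes from culture are not separated.

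Stimulation of Tsc1-deficient CD4 cells (n = 3 at each time) moved largely the same transcripts. Irf4 rose by 5.09 ± 0.14 (34-fold). Cxcl10 rose by 6.57 ± 0.37, Plagl1 by 5.48 ± 0.21 and Il2 by 4.40 ± 0.21, each from a level below the table median, so no fold is given. Afp fell by 5.37 ± 0.16 on the log2 scale, to below the table median, and Ccr9, high at rest in these cells, fell by 4.85 ± 0.19. Limma called 6041 genes, 2357 higher and 3684 lower, with 1876 changed at least 2-fold, and 6389 without the 2 arrays with high 3' to 5' ratios. With all probe sets tested 6894 were higher and 6789 lower. Of the wild-type calls, 1693 were higher in both genotypes, where independent lists would share 301, and 2820 were lower in both (704), while 14 were called in opposite directions. The fold changes of the genotypes correlated across genes (r = 0.904, Spearman's rho = 0.767), and genes are not independent replicates. These comparisons share no arrays, and simulated unchanged groups gave r = 0.000707. That low value is built in, since simulated arrays vary independently, and it takes no account of any shared preparation.

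In deficient cells Nr4a2 (4.81 ± 0.44), Fosl2 (4.75 ± 0.19), Nr4a3 (4.71 ± 0.21), Zfp948 (4.50 ± 0.25), Ramp3 (4.20 ± 0.24) and Gadd45b (3.92 ± 0.26) rose. Dtx1 (-4.91 ± 0.13), Pdlim4 (-4.11 ± 0.12), Slc40a1 (-3.99 ± 0.34), Hsd11b1 (-3.98 ± 0.11), Slc16a5 (-3.98 ± 0.17), Pglyrp2 (-3.86 ± 0.08), Sit1, an adaptor that dampens receptor signals (-3.86 ± 0.14), and Septin9 (-3.80 ± 0.12) fell. Slc40a1 and Slc16a5 ended below the table median, so their falls may be larger than given. Activation cytokines and receptors rose in 22 of 26 cases and 0 fell (22 and 0 adjusted over the list alone, adjusted p = 9.35e-16, and adjusted p = 7.07e-05 with an estimated correlation). Immediate early genes rose in 16 and fell in 5 of 25 cases (16 and 6 adjusted over the list alone, adjusted p = 3.62e-06, but adjusted p = 0.556 with an estimated correlation). Interferon response genes rose in 11 and fell in 2 of 23 cases (12 and 2 adjusted over the list alone, adjusted p = 0.00221, but adjusted p = 0.686 with an estimated correlation). Oxidative phosphorylation genes fell in 16 and rose in 1 of 26 cases (16 and 1 adjusted over the list alone, adjusted p = 0.00408, but adjusted p = 0.556 with an estimated correlation), and sterol genes fell in 12 and rose in 4 of 22 (13 and 4 adjusted over the list alone, adjusted p = 0.02, but adjusted p = 0.556 with an estimated correlation). Myeloid markers fell in 11 of 15 cases (11 adjusted over the list alone, adjusted p = 0.00656) and CD8 lineage genes in 4 of 5 (4 adjusted over the list alone, adjusted p = 0.02). Each of this last pair of lists had adjusted p = 0.556 with an estimated correlation.

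The difference between the stimulation responses of the genotypes was tested gene by gene. Il4 (1.60 ± 0.26, adjusted p = 0.00584), Ifng (1.57 ± 0.33, adjusted p = 0.024) and Csf2 (1.10 ± 0.25, adjusted p = 0.04) had a higher response in deficient cells. At rest all 3 lay below the table median in both genotypes, and Il4 and Csf2 did so in stimulated wild-type cells as well, so the size of these differences is uncertain. Irf4 rose less, with a difference of -1.43 ± 0.19 (adjusted p = 0.00137), starting from a level of 5.14 in unstimulated deficient cells against 4.18 in wild-type cells. Cd44 fell in wild-type cells and was at -0.24 ± 0.12 in deficient cells, a difference of 0.97 ± 0.17 (0.57 with its probe sets averaged, adjusted p = 0.0726). The call of Ifng was lost without any 1 unstimulated array but deficient replicate 3, or without stimulated wild-type replicate 2 (adjusted p = 0.0533 to 0.0748), and that of Csf2 without any 1 unstimulated or wild-type array (0.0645 to 0.102). Limma called 206 genes, 93 with a higher and 113 with a lower difference, and 78 of them by at least 2-fold. It called 325 without the 2 arrays with high 3' to 5' ratios, of which 183 were among the 206.

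Positive differences arose in several ways. Ramp3 (1.85 ± 0.34), Plagl1 (1.71 ± 0.30) and C9orf72 (1.62 ± 0.32) rose in both genotypes and by more in deficient cells, Plagl1 from below the table median. The interferon-induced Usp18 (1.89 ± 0.42) fell by 0.97 ± 0.30 on the log2 scale in wild-type cells and rose by 0.92 ± 0.30 in deficient cells. Lrrc75b (1.88 ± 0.21) fell in wild-type cells from 4.24 to 2.34 and in deficient cells was at 2.31 before and 2.29 after stimulation, below the table median. Usp18 lost its call without the 2 arrays (1.60, adjusted p = 0.0684) and without any 1 of 8 arrays (adjusted p = 0.0687 to 0.116), C9orf72 without wild-type unstimulated replicate 3 (0.0517) or deficient unstimulated replicate 2 (0.0515), and Plagl1 with its probe sets averaged (0.85, adjusted p = 0.0726). In the other direction stood genes that were high at rest in deficient cells, namely Fam221a (-2.35 ± 0.23), Hpgds (-2.31 ± 0.26), Patl2 (-2.15 ± 0.30), Adipoq (-2.14 ± 0.22) and Trpm1 (-1.98 ± 0.22). Hpgds and Adipoq lay below the table median in the other 3 CD4 groups, and Trpm1 in stimulated wild-type cells, so their differences largely repeat the level at rest and their size is uncertain. The death-promoting gene Bbc3 rose in wild-type and fell in deficient cells (-0.92 ± 0.18). Its call was lost without wild-type unstimulated replicate 1 (adjusted p = 0.0572), wild-type stimulated replicate 2 (0.0623), or deficient unstimulated replicate 2 (0.0576) or 3 (0.0539). 

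As lists, activation cytokines and receptors responded more in deficient cells, with 3 of 26 genes called (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.00567, but adjusted p = 0.073 with an estimated correlation). Interferon response genes had a median difference of 0.95 with 1 of 23 called (13 adjusted over the list alone, adjusted p = 2.34e-10, but adjusted p = 0.504 with an estimated correlation and 0.301 with fry). The mean of that list, to which Usp18 belongs, was 8.15, 7.63 and 7.22 on the unstimulated wild-type arrays and 7.35, 7.30 and 7.97 on the stimulated ones, so arrays of 1 group differed about as much as the responses. The ATF4 list stood higher (3 higher adjusted over the list alone, adjusted p = 0.0137), and the oxidative phosphorylation (0.00924) and DNA replication lists (0.0373) lower, with 0 genes called in each over all genes and 0 adjusted over the list alone in the last pair. Each of these 3 lists lost its call, at adjusted p = 0.504 with an estimated correlation and 0.301 with fry. Without the 2 arrays with high 3' to 5' ratios the ATF4 list (adjusted p = 0.083) and the DNA replication list (0.15) were no longer called. Over all genes 2017 had an unadjusted p under 0.05. Leaving out 1 array moved the count of 206 to between 103 and 287. It was 115 without wild-type unstimulated replicate 1, 109 without replicate 2, 112 without wild-type stimulated replicate 2, 115 without deficient unstimulated replicate 1 and 103 without replicate 2.

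Unstimulated Tsc1-deficient CD8 cells (n = 2) differed from wild-type CD8 cells (n = 2) in many of the genes that differed in CD4 cells. Myl10, a myosin light chain gene, rose by 3.90 ± 0.20 (14.9-fold, adjusted p = 2.44e-08), Fam221a by 3.45 ± 0.20 (10.9-fold) and Mki67 by 2.99 ± 0.19 (7.93-fold). Igfbp4 fell by 4.44 ± 0.24 on the log2 scale (adjusted p = 2.44e-08). Limma called 995 genes, 622 higher and 373 lower, with 191 changed at least 2-fold. Without the 2 arrays with high 3' to 5' ratios, 1 of which is deficient CD8 replicate 2, it called 1209 genes, of which 730 were among the 995.

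Trpm1 (3.11 ± 0.19), Rragd (2.76 ± 0.26), Patl2 (2.66 ± 0.26), Pcsk1 (2.55 ± 0.31), Pgpep1l (2.54 ± 0.20), Acot7 (2.54 ± 0.26) and Abcb1a (2.52 ± 0.25) rose in deficient CD8 cells. Lrrc75b (-2.39 ± 0.18), the costimulatory ligand Cd86 (-1.83 ± 0.25), Cxxc5 (-1.77 ± 0.23), Rhob (-1.56 ± 0.29), the lysosomal channel Mcoln3 (-1.42 ± 0.17), the cytokine receptor chain Il6st (-1.41 ± 0.11), Scg5 (-1.41 ± 0.13), Ttc28 (-1.37 ± 0.18) and Spred2 (-1.36 ± 0.23) fell. Pcsk1 began below the table median. Rhob lost its call without wild-type replicate 1 (-1.48, adjusted p = 0.0593). Lysosome genes rose in 9 of 21 cases (13 adjusted over the list alone, adjusted p = 1.48e-10, and adjusted p = 0.0296 with an estimated correlation, or 0.0663 with the Gapdh 3' to 5' difference as a covariate as well, with which the median change went from 0.396 to 0.380 and 10 members were called), led by Lamp2 (1.51 ± 0.14), Hexa (1.16 ± 0.12) and Ctsd (1.14 ± 0.13). Mitosis genes rose in 14 of 28 cases (18 adjusted over the list alone, adjusted p = 1.04e-18, but adjusted p = 0.0605 with an estimated correlation), with Birc5 at 2.40 ± 0.31 and Ube2c at 2.39 ± 0.38, the latter from below the table median. DNA replication genes rose in 10 of 28 cases (15 adjusted over the list alone, adjusted p = 2.38e-08, but adjusted p = 0.0692 with an estimated correlation), led by Rrm2 (2.48 ± 0.21). Sterol genes rose in 4 of 22 cases (10 adjusted over the list alone, adjusted p = 3.18e-06, but adjusted p = 0.0605 with an estimated correlation), led by Cyp51 (1.46 ± 0.17).

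Of 19 mTOR components, Rragd, Sesn2 (0.80 ± 0.19), Sesn1 (0.71 ± 0.18) and Rptor, a subunit of mTORC1 (0.70 ± 0.11), rose in CD8 cells (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.00589, but adjusted p = 0.137 with an estimated correlation). Without any 1 CD8 array Sesn2 (adjusted p = 0.0547 to 0.173) and Sesn1 (0.0741 to 0.193) lost their calls. ATF4 targets rose in 4 of 25 cases (8 higher and 3 lower adjusted over the list alone, adjusted p = 0.0139, but adjusted p = 0.497 with an estimated correlation and 0.0563 without the 2 arrays). Oxidative phosphorylation genes rose in 2 of 26 cases (2 adjusted over the list alone, adjusted p = 0.00785, but adjusted p = 0.66 with an estimated correlation). Effector and memory genes rose in 6 and fell in 1 of 28 cases (9 and 2 adjusted over the list alone, adjusted p = 0.0329, but adjusted p = 0.53 with an estimated correlation), led by S100a6 (1.81 ± 0.29). The chemokine genes Ccl3 (1.92 ± 0.24, from below the table median) and Ccl4 (1.55 ± 0.28) rose and the activation marker Cd69 fell (-0.91 ± 0.25), in a list of 26 that did not pass (adjusted p = 0.185). Cd69 lost its call without either wild-type array (adjusted p = 0.172 and 0.166) or deficient replicate 1 (-0.49, adjusted p = 0.31). No neutrophil gene passed limma's test. Ngp stood at 2.09 ± 0.82 (adjusted p = 0.167) and S100a8 at 1.90 ± 0.78 (adjusted p = 0.186), with 0 of 11 adjusted over the list alone and a list p of 0.171. Myeloid markers (adjusted p = 0.928) and quiescence genes (0.532) did not pass.

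With 2 arrays per genotype the CD8 count rests on single arrays. It was 305 without wild-type replicate 1 and 459 without wild-type replicate 2, with the lone array assumed to vary like the other groups, and 269 when only the compared groups entered the fit. Deficient replicate 2 had a Gapdh 3' to 5' difference of 0.64, and without deficient replicate 1 the calls were 384 higher and 537 lower.

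The genotype effects in unstimulated CD4 and CD8 cells, which share no arrays, correlated across genes (r = 0.621, Spearman's rho = 0.414, covariance 0.0519), against r = 0.00106 and a covariance of 2.68e-05 for simulated unchanged groups. Simulated arrays vary independently, so those low values are built in and take no account of mice or sorts that the lineages may share. Of the calls, 342 genes were higher in both lineages, where independent lists would share 24.6, and 119 were lower in both (6.98), with 0 in opposite directions. Of the 997 genes called in CD4 cells, 94.5% changed with the same sign in CD8 cells, against 61.5% of all genes.

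**Figure D4:**
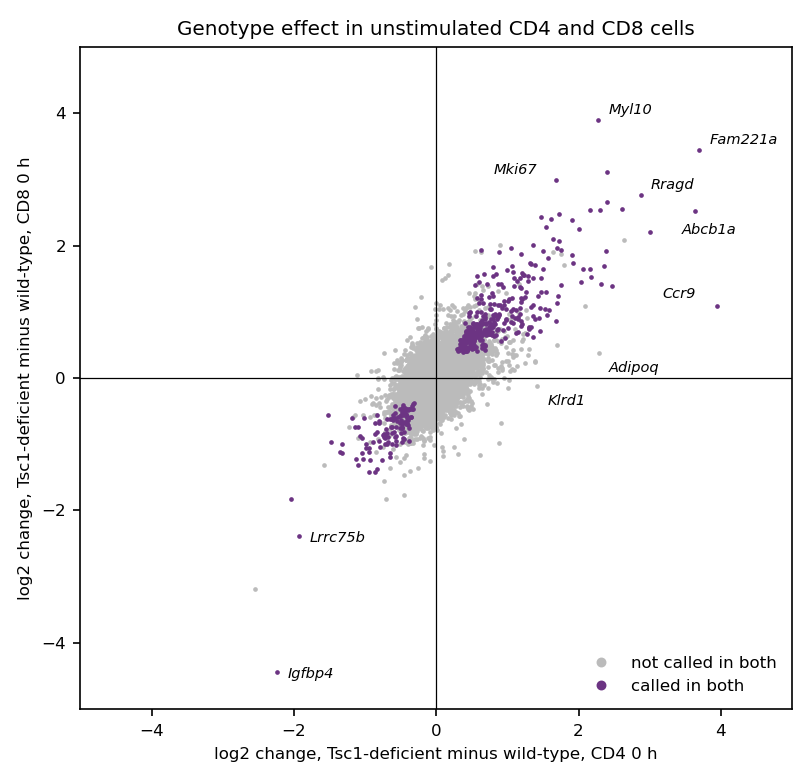
Log2 change, Tsc1-deficient minus wild-type, of each of 17097 genes in unstimulated CD4 (x axis) and CD8 cells (y axis), with genes called in both lineages in purple. Points lie along the diagonal (r = 0.621), while Ccr9 changed by 3.94 in CD4 and 1.08 in CD8 cells and Igfbp4 by -2.24 and -4.44.

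A test of the difference between the CD8 and CD4 genotype effects called 20 genes, 12 higher and 8 lower in CD8, and 17 of them by at least 2-fold. Ccr9 rose less in CD8 cells (difference -2.86 ± 0.30, adjusted p = 0.000775), where its wild-type level was already 10.7 against 6.67 in wild-type CD4 cells. Klrd1 rose in CD4 cells and was at -0.12 ± 0.13 in CD8 cells (difference -1.54 ± 0.17), from a wild-type level of 11.7 in CD8 and 8.87 in CD4 cells. Igfbp4 (-2.20 ± 0.31), the fat cell hormone gene Adipoq (-1.90 ± 0.25) and Tmtc4 (-1.20 ± 0.21) had lower differences as well. The glutamate receptor gene Gria3 (1.74 ± 0.23), Myl10 (1.63 ± 0.26), the lipid transfer protein Pltp (1.44 ± 0.19), the microtubule regulator Stmn1 (1.31 ± 0.15) and Mki67 (1.31 ± 0.24, adjusted p = 0.0492) had higher ones. Adipoq in both CD8 groups, and Gria3 and Pltp in both CD4 groups, lay below the table median, so the genotype effect of that lineage is not measured and the size of these differences is uncertain. Mitosis genes stood higher in the CD8 effect (median difference 0.30, 1 of 28 called, 1 adjusted over the list alone, adjusted p = 0.00537), with adjusted p = 0.747 with an estimated correlation. The count was 31 without the 2 arrays with high 3' to 5' ratios, with 12 of the 20 among them, and between 7 and 24 when 1 array was left out. The balance moved with the deficient CD8 arrays, with 5 higher and 19 lower without replicate 1, and 15 higher and 4 lower without replicate 2. Mki67 was no longer called without the 2 arrays (1.16, adjusted p = 0.203) or without any 1 array (0.0533 to 0.253), Tmtc4 without any 1 array but deficient CD8 replicate 1 (0.0809 to 0.238), and Igfbp4 without wild-type CD8 replicate 1 (-2.05, adjusted p = 0.0638). Myl10 lost its call without wild-type CD4 replicate 1 or 3, deficient CD4 replicate 3, either wild-type CD8 array or deficient CD8 replicate 1 (0.0525 to 0.19).

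**Figure D5:**
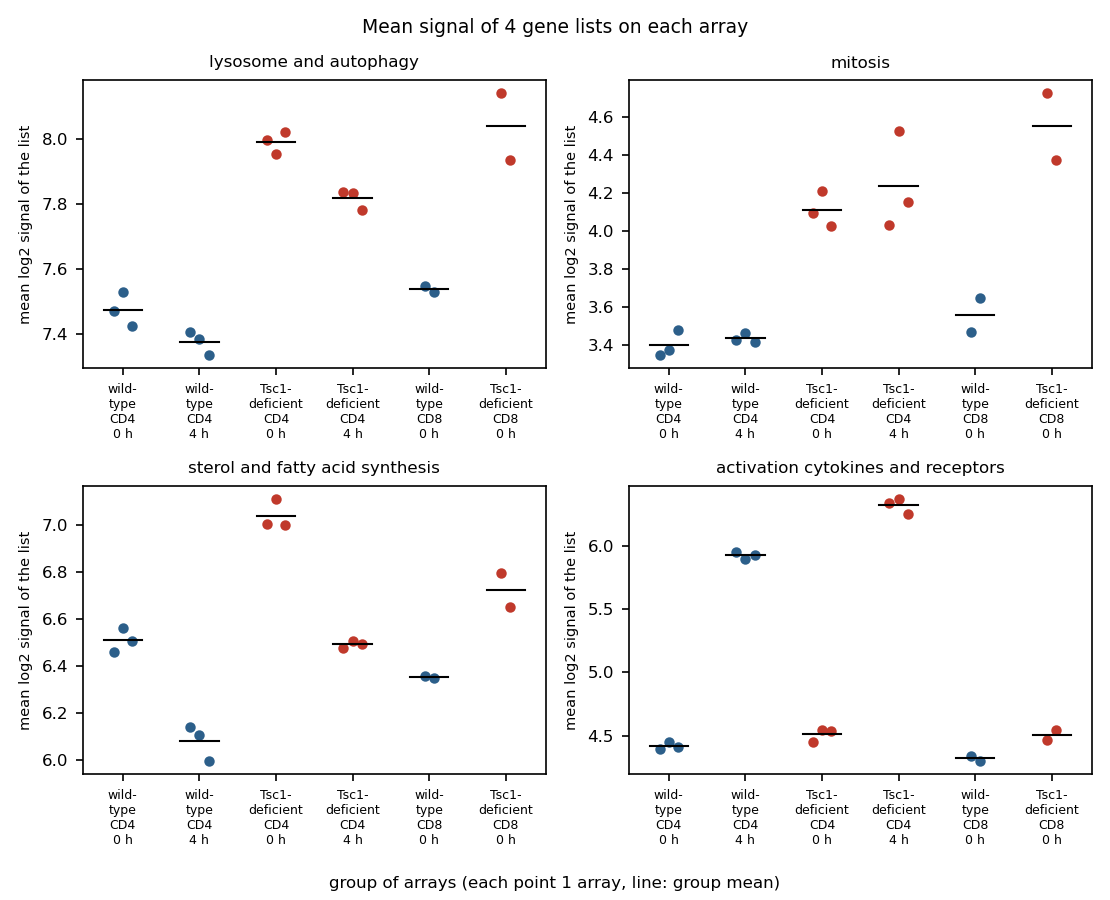
Mean log2 signal of 4 gene lists (y axis) on each of the 16 arrays by group (x axis, blue wild-type, red Tsc1-deficient, line at the group mean). In unstimulated CD4 cells the mitosis list lies between 3.35 and 3.48 on wild-type arrays and between 4.03 and 4.21 on deficient ones.

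The last comparison asks whether resting Tsc1-deficient cells resemble stimulated wild-type cells. Across genes, the resting CD4 genotype effect and the wild-type stimulation response were close to uncorrelated (r = 0.0264, Spearman's rho = 0.0649). Both use the unstimulated wild-type CD4 arrays, and unchanged groups simulated with that sharing gave r = 0.5. Those groups hold no real changes, so their r is not a reference for an r that real changes dilute. The observed covariance was 0.00416 and the simulated one 0.0105, a difference of -0.00629. Of the 997 genes called at rest, 47.1% changed with the same sign under stimulation, against 55.5% of all genes. By sign, the called genes therefore showed no excess of resemblance. Of the 677 genes higher at rest in deficient cells, 135 rose with stimulation (independent lists would share 86.4) and 272 fell (129), and of the 320 lower genes, 61 rose (40.8) and 169 fell (61.2). Each overlap exceeded its independent count, in the same and in opposite directions, so the excess alone does not show resemblance. Among genes higher in both were Irf4 and Bhlhe40, while Ccr9 and Hpgds were higher at rest in deficient cells and fell with stimulation. Hpgds lay below the table median in wild-type cells before and after stimulation, so its fall may be near background. The control groups of 3 arrays cannot be split into separate sets of at least 2. Part of the overlaps in the same direction (135 and 169 genes) may therefore come from the shared arrays. Sharing would lower, not raise, the overlaps in opposite directions (272 and 61 genes). The CD8 genotype effect, which shares no arrays with CD4 stimulation, gave r = -0.00133 and rho = -0.0417, and of its 622 higher genes 122 rose with CD4 stimulation (79.4) and 236 fell (119). Of its 373 lower genes, 74 rose (47.6) and 170 fell (71.3), so every pair of directions again exceeded independence. Of its 995 called genes, 47.6% changed with the same sign under CD4 stimulation, against 48.5% of all genes.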

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

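The tests of myeloid cells, neutrophil-lineage cells, antigen-experienced cells, variation of cell-cycle transcripts between arrays, and RNA quality in CD8 cells were chosen after the results were seen, while the tests by other splits were not. The test of RNA quality in CD4 cells was posed for a lysosome result already seen, with its prediction written before its own result.

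The stimulation responses of the genotypes differed by a test of the difference itself for 206 genes. Ramp3 (1.85), Plagl1 (1.71) and C9orf72 (1.62) rose by more in Tsc1-deficient cells, Usp18 (1.89) rose in deficient and fell in wild-type cells, and Lrrc75b (1.88) fell in wild-type cells alone, from a level that deficient cells did not have at rest. Fam221a (-2.35), Hpgds (-2.31), Patl2 (-2.15), Adipoq (-2.14) and Trpm1 (-1.98) had negative differences, of uncertain size for Hpgds, Adipoq and Trpm1, which lay below the table median in 1 or more of the 4 groups. Of 100 drawn reassignments of genotype within each time, 5 called at least 206 genes, the real one included, with 2324 as the highest other. The 4 others kept the genotypes whole at 4 h, which carries the genotype effect itself into the difference, while the 80 that mixed genotypes at both times called 0 genes but take that effect into their spread. These splits therefore do not settle whether chance can be excluded for this count.

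The genotype effects of the lineages differed for 20 genes, again by a test of the difference. Gria3 (1.74), Myl10 (1.63), Pltp (1.44), Stmn1 (1.31) and Mki67 (1.31) had a higher effect in CD8 cells, and Ccr9 (-2.86), Igfbp4 (-2.20), Adipoq (-1.90), Klrd1 (-1.54) and Tmtc4 (-1.20) a lower one. For Gria3, Pltp and Adipoq both groups of 1 lineage lay below the table median, so its effect is not measured.

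For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and in each of them 1 split, the real one, reached the real count. The real and the highest other counts were 997 and 0 for genotype at rest, 1616 and 1 for genotype after stimulation, 5451 and 0 for wild-type stimulation, and 6041 and 0 for deficient stimulation. Every other split mixes the compared groups and takes their difference into its spread, which keeps its count low by construction. These counts therefore do not settle whether chance can be excluded.

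Lysosome genes were higher in unstimulated deficient cells. The test assumed that more monocytes, macrophages or dendritic cells in the sorts would raise their markers at least as much. That premise was not tested and may fail for markers near background. The median change of 15 such markers was below that of the lysosome list by 0.174 in CD4 cells (difference -0.174, between -0.328 and -0.133 without 1 array) and by 0.382 in CD8 cells (difference -0.382, between -0.607 and -0.293). If the premise holds, this argues against such cells as the whole source. With the Gapdh 3' to 5' difference as a covariate the CD4 list had a camera adjusted p of 0.0203 with an estimated correlation (median change 0.40 before and 0.396 after). That difference was 0.118 to 0.234 on the deficient and 0.111 to 0.204 on the wild-type unstimulated CD4 arrays. The covariate could therefore move the change little, and its result decides nothing. The overlap of the ratio itself argues against RNA quality, as this ratio measures it, in CD4 cells. In CD8 cells the covariate ended the call with an estimated correlation, at adjusted p = 0.0663 against 0.0296, because that correlation rose from 0.087 to 0.157, while the median went from 0.396 (quartiles 0.165 and 0.852) to 0.380 (0.175 and 0.826), the members called higher from 9 to 10 and the adjusted p at the preset correlation from 1.48e-10 to 1.15e-10. The mean of the list per CD8 array differed by 0.499 ± 0.058 before and 0.501 ± 0.061 after (95% interval 0.363 to 0.639, with its lower end at 0.275 or more without any 1 CD8 array). The Gapdh difference was 0.28 and 0.64 on the deficient and 0.39 and 0.40 on the wild-type CD8 arrays. The covariate could therefore move the group difference little, and it does not settle RNA quality in CD8 cells. The control signal for the 5' end of 18S RNA was 10.96 on deficient CD8 replicate 2 and 12.16 to 12.92 on the other CD8 arrays, and was not used as a covariate. A response of the T cells to Tsc1 loss stays a hypothesis.

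Of 11 neutrophil genes, 4 were higher in stimulated deficient CD4 cells, with a list call that was lost with an estimated correlation (adjusted p = 0.353) and with fry (0.0749). At rest only Ngp passed, and its call was lost without wild-type replicate 1 (adjusted p = 0.0931), wild-type replicate 2 (0.15) or deficient replicate 3 (0.134). For 6 of these genes the deviations from their group means rose and fell together across the 16 arrays (median pairwise correlation 0.893). The 6 were chosen for a group mean above the median level and a higher mean in unstimulated deficient CD4 cells. The arrays may share preparations, so they may not be independent. Neutrophil-lineage cells or their RNA in some sorts would give this pattern. A naive T cell sort is meant to remove such cells, but its purity was not measured here. S100a8 was higher on every deficient than on every wild-type array in stimulated CD4 cells (lowest 6.70 against highest 4.95) and in CD8 cells (6.95 against 6.66), while unstimulated CD4 cells overlapped (6.14 against 6.43), and within each CD4 group replicate 3 was the highest. Whether such RNA came with genotype or with the sorts stays open, since each array holds cells of 1 genotype.

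Of 28 mitosis genes, 10 were higher in unstimulated deficient CD4 cells, with a list call that was lost with an estimated correlation (adjusted p = 0.0659). The lowest deficient array exceeded the highest wild-type array by 0.546 in the mean of the list, but a list called higher on the same arrays is bound to separate them, so this gap alone decides nothing. On other arrays, the mean was 3.42 to 3.46 in stimulated wild-type CD4 cells and 4.03 to 4.53 in deficient ones. In CD8 cells it was 3.47 and 3.65 in wild-type and 4.73 and 4.38 in deficient cells. The separation thus recurred on these arrays. The list was called higher on them too, and the labels do not say whether the arrays share mice. The separation therefore does not exclude a level of this list that varies between arrays whatever the genotype. Antigen-experienced cells in the deficient sorts stay open and may contribute. A naive T cell sort is meant to remove them, but its purity was not measured here. The effector and memory list does not decide it, with an adjusted p of 0.202 with an estimated correlation, and 9 members higher and 3, Cd44 among them, lower. Cycling within naive cells is the biological alternative, as a hypothesis.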

How the results depend on the processing

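The alternatives without the 2 arrays with high 3' to 5' ratios, and with that ratio as a covariate, were chosen after the control probe sets were seen. The self-test gives what array number and noise limit for genes above the median level, and dim probe sets lie near background.

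Of 130 alternatives for counts of genes, 93 stayed within 1.5 times the reported count. With array weights 1937 genes differed by genotype at rest and 351 in response to stimulation. Without the 2 arrays the counts were 1723 at rest, 325 for the difference in response and 31 for the difference between lineages. Testing all probe sets called 2564 probe sets (genotype after stimulation), 12112 (wild-type stimulation) and 13683 (deficient stimulation). These are counts of probe sets, which do not compare directly with counts of genes. They were made up of 6000 higher and 6112 lower for wild-type and 6894 and 6789 for deficient stimulation, nearer to even than with 1 probe set per gene. With only the compared groups in the fit 823 genes differed after stimulation and 269 in CD8 cells, but 1415 at rest and 6003 under wild-type stimulation. Asking for a 2-fold change as well left 161, 195, 1526, 1876, 78 and 191 genes in the order genotype at rest, genotype after stimulation, wild-type and deficient stimulation, difference in response, and CD8 genotype. Only genes above the median level left 11 genes for the difference between lineages. Of 182 list tests 52 passed, 13 with the estimated correlation, which is wider by construction, and 66 with fry. For the other moved counts the cause was not tested.

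Leaving out 1 array in turn gave 589 to 704 genes for genotype at rest, 1062 to 1715 after stimulation, 4853 to 4938 for wild-type and 5452 to 6070 for deficient stimulation, 103 to 287 for the difference in response, 305 to 921 for CD8 genotype and 7 to 24 for the difference between lineages. A lone CD8 array is assumed to vary like the other groups. The correlation of the resting genotype effect with the stimulation response was 0.0162 to 0.0543 without 1 array, 0.00852 for genes above the median level, and -0.00133 with the CD8 effect in its place.

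For 442 results named by rule, each a called gene in a given comparison, 7294 alternatives kept the direction and call in 6862 and lost the call in 431. A gene named in several comparisons counts once in each. The exception was Atp5c1, -0.64 under wild-type stimulation and 0.098 with its probe sets averaged (adjusted p = 0.663), as its probe sets differ.

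The labels do not pair the arrays, and a replicate block of neighbouring sample codes was tried. Residual correlations were 0.03 to 0.077 in the 6 pairs, each array matching its own code best, a hint from the data alone, and the counts with the block were 5346 and 5933 for stimulation and 143 for the difference in response.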

Other observations

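The further gene families here were chosen after the results were seen. The TFEB and TFE3 target test was posed for a lysosome result already seen, with only its prediction written before its own result.

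Subunits of the vacuolar ATPase, the proton pump that acidifies lysosomes, were higher in unstimulated Tsc1-deficient CD4 cells (n = 3 arrays per genotype). Of 20, 8 were called higher and 0 lower by limma (median 0.25, camera adjusted p = 2.36e-08, and adjusted p = 0.0421 with an estimated correlation). In CD8 cells 6 were higher (adjusted p = 2.57e-05, but adjusted p = 0.168 with an estimated correlation), and 6 in stimulated CD4 cells (4.77e-05, and adjusted p = 0.12 with an estimated correlation). Proteasome subunits were higher at rest in 8 of 37 cases in CD4 cells (4.06e-09, but adjusted p = 0.211 with an estimated correlation) and in 6 in CD8 cells (4.08e-07, and adjusted p = 0.35 with an estimated correlation). Mitochondrial ribosomal proteins were higher in 11 of 73 cases in unstimulated CD4 cells (2.36e-08, but adjusted p = 0.512 with an estimated correlation), and fell in 42 and rose in 3 when deficient cells were stimulated (5.37e-06, but adjusted p = 0.9 with an estimated correlation). They fell in 29 and rose in 6 when wild-type cells were stimulated (0.0167, but adjusted p = 0.808 with an estimated correlation), and the test of the difference gave 3.28e-06 with 1 gene called, and adjusted p = 0.81 with an estimated correlation.

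A hypothesis for the lysosome genes is that TFEB and TFE3, transcription factors of lysosome biogenesis, are more active in Tsc1-deficient cells. If so, further known targets outside the fixed lists would be higher too. The 29 targets tested are themselves lysosomal genes, 6 of them subunits of the vacuolar ATPase, but for Fnip1, Fnip2 and Rragc. Of these 29, 13 were called higher and 0 lower in unstimulated CD4 cells (median 0.40, adjusted p = 0.00057 with an estimated correlation), 12 in CD8 cells (0.00304) and 12 in stimulated CD4 cells (0.00149). Any other cause that raises lysosome genes would raise these as well, so the test does not tell TFEB and TFE3 from such a cause, and protein activity was not measured here.

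The mean of the immediate early list was 6.35, 6.41 and 6.54 on replicate 1 of the unstimulated wild-type CD4, deficient CD4 and deficient CD8 cells, and 6.80 to 7.06 on the other unstimulated arrays. The mean of the interferon list was 8.15, 7.63 and 7.22 on the unstimulated wild-type CD4 arrays. Hif1a, named in the treatment text, changed by 0.14 (adjusted p = 0.522), 0.23 (adjusted p = 0.166) and -0.10 (adjusted p = 0.716) with genotype in unstimulated CD4, stimulated CD4 and CD8 cells.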
